A study of Mus musculus with 6 samples.

How the data were processed

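The data were polyadenylated RNA of sorted mouse lung tumour cells in 6 libraries, 3 from animals given a control dRNA and 3 from animals given the mA1 dRNA, each library from a different animal. Per the labels' protocols, RNA was treated with DNase and libraries were made with a low-input kit, which does not mark strand. Per the submitters' processing notes, mm10, TopHat2 2.1.1, HTSeq 1.99.2 and DESeq2 were used, and the notes used here give these names no roles. The annotation, strand setting and gene filter of the counting were not given in the sources used here. Groups and replicate numbers were taken from the sample labels, and table columns were matched to samples by treatment and number.

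Both deposited tables, one of exonic and one of intronic reads per gene, hold normalised signal values: per the file headers and the values, the authors divided read counts by one size factor per library. In every library 100% of values were whole multiples of one step to a tolerance of 0.05, so whole reads were recovered. In exonic columns of mA1 libraries 2 and 3 that step is 1.01, close to 1, so that whole reads are harder to tell from the values there, and 18.4% and 18.7% of values would be whole without the step. The same holds for exonic control library 1 (step 0.988, 20.3%) and intronic mA1 library 3 (step 0.987, 17.8%). The other deposited columns are the authors' own comparison, per the file headers: a log2 fold change with its standard error, a test score that divides one by the other, a p-value and an adjusted p-value. The deposited mean over libraries was not used. The smallest sum of recovered reads per gene was 20 in exons and 23 in introns. Gene names matched the annotation for 17158 of 17842 exonic genes (96.2%) and 13275 of 13738 intronic genes (96.6%), and 19 and 18 names had been turned into dates by spreadsheet software. Malat1, Neat1 and genes of chromosomes X, Y and the mitochondrial genome were not analysed here.

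The plan fixed before the data were examined named edgeR for raw counts and limma on log2(value + pseudocount) otherwise. Because the values are normalised, limma 3.58.1 in R 4.3.3 was used with a mean-variance trend on log2(value + 10), for genes with a value of at least 10 in at least 3 libraries, and p was adjusted by the Benjamini-Hochberg method at 0.05. The pseudocount and the filter were chosen after the files were seen. For the exon against intron comparison limma was run on the difference of the log2 values of each library. edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) were run on recovered reads as alternatives. The p-values of single genes come from these models, and camera adjusted p come from limma's camera. The share of intronic reads was compared by an exact permutation test.

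Gene lists, 28 in number, were fixed before the data were examined, and 27 had members to test: Malat1 neighbours, chemokines and cytokines, NF-kB targets, interferon response, class I and class II antigen presentation, alveolar type 2, alveolar type 1, airway, gastric endoderm, late-stage plasticity, mesenchymal, epithelial junction, proliferation, MAP kinase output, hypoxia and glycolysis, immediate early, nuclear speckle, nuclear-retained RNA, ribosomal proteins, and markers of macrophages, neutrophils and monocytes, lymphocytes, endothelium, fibroblasts and mural cells, erythroid cells and platelets, and mesothelium. The list of mitochondrially encoded genes was not analysed here. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. Fry's directional test passed 0 lists (smallest adjusted p = 0.368), and its mixed test, which asks for change in either direction, passed 3 lists: nuclear-retained RNA (adjusted p = 9.83e-05), nuclear speckle (adjusted p = 0.000991) and endothelium (adjusted p = 0.0209).

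The rule for named genes, also fixed before, took measured Malat1 neighbours, the 12 genes that rose and the 12 that fell most among passing genes with a mean CPM of at least 5 and no overlap between groups, or the 10 genes with the smallest p where fewer than 6 passed. It took passing list members, at most 6, or else up to 3 abundant ones as values, Ccl2 always, 5 intronic genes per direction, and 5 genes per direction for exon against intron. As 1 exonic gene passed, the 10 with the smallest p were taken, and the size ranking was applied also to the authors' calls after their values were seen. Results for some genes that the rule covers are not reported here.

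Gene positions came from GENCODE M21 on GRCm38. Transcript GC content and length were those of the longest transcript, and 12041 genes with a mean value of at least 100 entered the GC check. The GC correction fitted a natural spline with 5 degrees of freedom per library. A fold against a group at 0 was computed against 3 reads in each library of that group, and ratios of few reads have an exact 95% interval. Alternatives covered scaling, test, filter, pseudocount, GC correction, library weights, the replicate number as a block, and leaving out each library.

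The tests were tried on simulated counts for the real genes with 200 changed genes. For exons limma recovered 12.8% of genes changed 2-fold, 61.0% of those changed 4-fold and 77.4% of those changed 8-fold, and 7 of its 101 calls were false. DESeq2 recovered 34.6%, 79.7% and 88.9% in exons, with 80 of 210 calls false, and edgeR 6.41%, 59.3% and 77.4%, with 3 of 91 false. For introns limma recovered 1.37%, 50% and 66.7%, with 9 of 83 calls false, and DESeq2 5.48%, 69.7% and 86.9%, with 61 of 164 false. For exon against intron limma recovered 0%, 0% and 4.17%. Camera recovered the shifted list and called 0 of 27 lists without the shift. The simulated genes were drawn independently, so this does not show how often camera calls unshifted lists when genes vary together. Tables were handled with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.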

Results

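Polyadenylated RNA was measured in tumour cells sorted from a genetically engineered mouse model of lung adenocarcinoma in which p53 is lost and the tumour cells carry Cas9 and GFP. The sorted cells were alive, lacked CD45 (a leukocyte surface protein) and carried Epcam (an epithelial adhesion protein) and GFP, and they were collected 16 weeks after tumours were started. The 6 libraries came from different animals, 3 given a control dRNA and 3 given the mA1 dRNA, the reagent with which the series set out to raise Malat1, a long noncoding RNA of the nucleus. Recovered exonic reads ranged from 71093708 to 85248140 per library and recovered intronic reads from 7200660 to 11422283. Exonic reads were found for 16525 to 17302 genes per library, intronic reads for 12776 to 13363, and the 10 most abundant genes took 12.7% to 22.6% of exonic reads. Values are normalised read counts, given as mean ± SD with n = 3 libraries per group, and positions are on GRCm38 (mm10) from GENCODE M21. Log2 fold changes are mA1 over control on the log2(value + 10) scale, which understates changes of low genes. The reads carried no molecular identifiers, so intervals and floors cover counting error only.

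The first comparison asked how the transcriptome of the tumour cells differed after the attempt to raise Malat1. Malat1 itself, its neighbour Neat1 and genes of chromosomes X and Y and of the mitochondrial genome were not analysed here, so the group labels were not checked against the targeted gene. Of the 12 listed genes around the Malat1 locus on chromosome 19, 9 were measured, and 6 of them had lower and 3 higher mean values in mA1 libraries. Map3k11, a kinase of the JNK pathway (chromosome 19, 5688742 to 5702865, plus strand), had 4326 ± 183 normalised counts in control and 1417 ± 622 in mA1 libraries, a log2 fold change of −1.72 (SE 0.36). It was the 1 neighbour past 0.05 adjusted over the list alone (limma adjusted p = 0.0175), against 0 over all genes tested (limma adjusted p = 0.237). The authors' deposited table gives Map3k11 a log2 fold change of −1.61 and an adjusted p of 0.00251. Ehbp1l1 (−1.04), Cdc42ep2 (−1.13) and Frmd8 (−0.53) also had negative log2 fold changes, while Tigd3 (0.75) and Slc25a45 (0.13) had positive ones. Dpf2 (0.0310) and Ltbp3 (−0.0867) lay near 0 and changed sign when a library was left out or GC content was corrected. The kit does not mark strand, and the count of Ltbp3 is uncertain for that reason. As a set the neighbours fell, with a median of −0.38 (camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted p = 0.0269), and this call was lost with an adjusted p = 0.691 with an estimated correlation. The set's camera adjusted p was 0.0610 without control library 1 (median −0.37), 0.09997 without control library 2 (−0.35) and 0.221 after GC correction (−0.17). Without mA1 library 2 the median was −0.18.

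Across exons, 1 of 16606 genes passed, Ly6d, which encodes a GPI-anchored surface protein of the Ly6 family (chromosome 15, 74762056 to 74763620, minus strand). Ly6d fell from 45714 ± 5891 normalised counts in control to 11445 ± 785 in mA1 libraries, a log2 fold change of −1.99 (SE 0.14; limma, Benjamini-Hochberg adjusted p = 0.0252). The groups did not overlap: control libraries held 40060, 51817 and 45264 and mA1 libraries 12306, 10769 and 11260 normalised counts of Ly6d. The call was lost in edgeR on recovered reads, where Ly6d had adjusted p from 0.0582 to 0.0648 over 3 scalings. It was also lost when any library but control library 1 was left out (limma adjusted p from 0.0777 to 0.302, and 0.0220 without control library 1). The replicate block ended it too (limma adjusted p = 0.301, and 0.261 with GC correction as well). At an unadjusted limma p under 0.05 there were 2096 genes, 856 higher and 1240 lower. Other tools differed: edgeR's quasi-likelihood test with TMM factors called 0 genes (1741 at unadjusted p under 0.05), limma-voom 1, and DESeq2 478 (140 higher and 338 lower). The balance of the DESeq2 calls depended on single libraries, with 347 higher and 308 lower without control library 3 and 127 and 643 without mA1 library 3.

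The next 9 genes by p did not pass (limma adjusted p from 0.0998 to 0.182), although their groups did not overlap. Prtg, protogenin, a cell-surface protein of the early embryo (chromosome 9, 72806874 to 72917291), had 2 recovered reads over the control libraries and 830 over the mA1 libraries, a ratio of 399.7 (95% interval 110.3 to 3306). Hal, the histidine ammonia-lyase gene (chromosome 10, 93488768 to 93519304), had 179 ± 73.7 normalised counts in control and 0 in every mA1 library, at least 61.7-fold lower against a floor of 3 reads in each library. By the same floor Npy4r, a neuropeptide receptor gene, was at least 60.0-fold lower and Oprd1, the delta opioid receptor gene, at least 48.0-fold lower. H2-Eb2, a class II histocompatibility gene, had 0 in every control library and 94.2 ± 26.2 in mA1 libraries, at least 31.2-fold higher, and is uncertain because its family shares sequence. Zbtb7b, a zinc finger transcription factor gene (chromosome 3, 89377644 to 89394776), had 2383 ± 216 and 940.1 ± 24.5 normalised counts. The noncoding gene 1700049E15Rik (chromosome 6, 147690241 to 147702374) had 32.9 ± 23.2 and 753 ± 159, and C130075A20Rik (chromosome 3, 53099000 to 53103175), which lies within Lhfp on the same strand and is uncertain for that, had 3.53 ± 3.61 and 286 ± 136. The processed pseudogene Gm21769 had 2787 ± 222 and 6352 ± 928 and is uncertain as one of many similar copies.

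**Figure D1:**
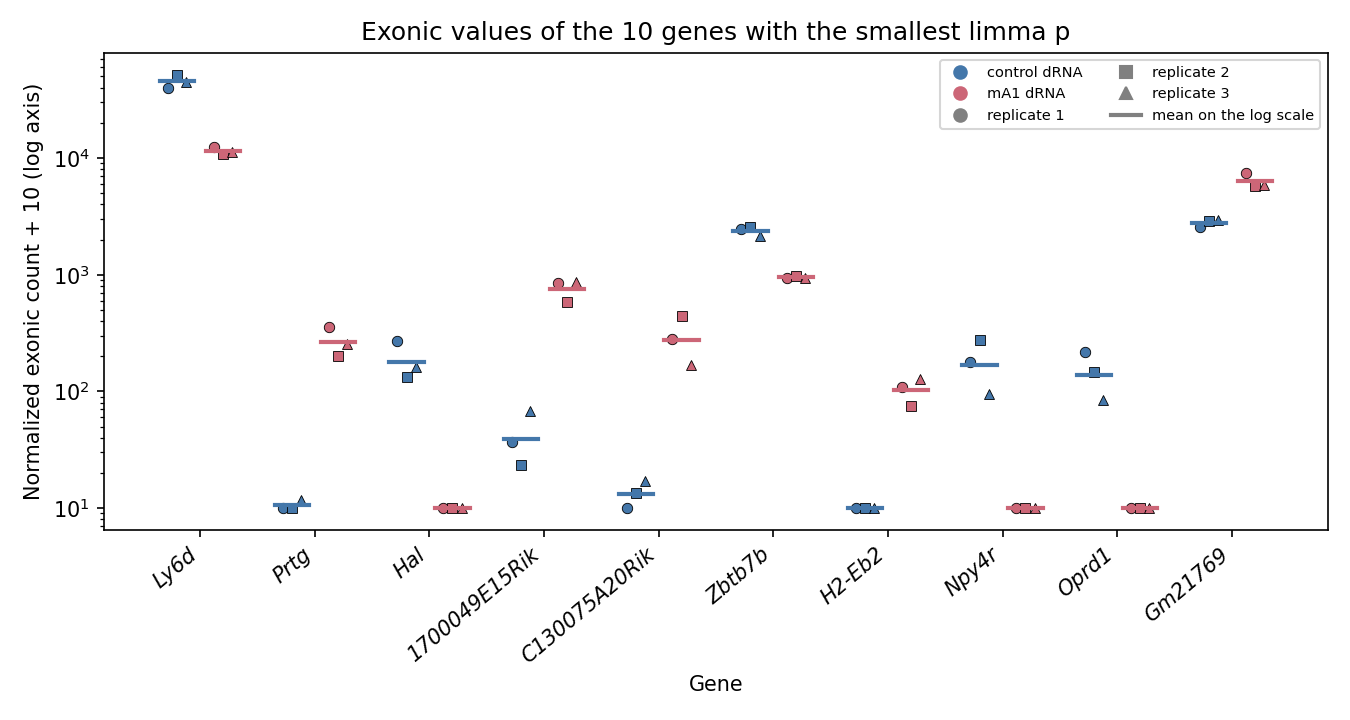
Normalised exonic count plus 10 (log axis) for each of the 6 libraries in the 10 genes with the smallest limma p, with lines at the group means on the log scale. Ly6d, the 1 gene past the threshold, has 40060 to 51817 in control and 10769 to 12306 in mA1 libraries.

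The authors' deposited table holds a larger set of exonic calls, 496 genes past adjusted p 0.05, of which 144 were higher and 352 lower in mA1 libraries. In 489 of these 496 calls of the authors' deposited table the groups did not overlap, a pattern found in 18.4% of all genes where chance gives 10%, and in 46 every library of one group was at 0. DESeq2 on the recovered reads called 478 genes, all of them among the 496. The genes that stood out in size among the authors' calls were picked after their values were seen, by the ranking fixed for passing genes. On the higher side of the authors' deposited table were 1700049E15Rik (log2 fold change 4.51), Ppargc1a (3.10), a coactivator of mitochondrial biogenesis, Guca2a (3.04), the gut peptide guanylin, and the complement protease gene C1s1 (2.77). Sectm1b, Ly6i, Gm42899, BC048546, Tmem64, Fgl1, Napb and Gm42735 followed, with log2 fold changes from 2.32 to 1.70 in the authors' deposited table. On the lower side of the authors' deposited table were Sox17 (−3.87), an endodermal and endothelial transcription factor, the claudin gene Cldn9 (−3.40), Slfn4 (−3.19), the small GTPase gene Rhoj (−2.92) and Tff3 (−2.74), a trefoil peptide of mucosal epithelia. Tmem150c, the amino acid transporter gene Slc16a10, Atp10b, Pzp, the apolipoprotein gene Apoc2, Ank1 and the homeobox gene En1 followed, from −2.67 to −2.38 in the authors' deposited table. Of these 24 genes 20 were still called by DESeq2 after GC correction and 17 without control library 1. Sox17 had 2910 ± 1074 normalised counts in control and 199 ± 172 in mA1 libraries, Tff3 10312 ± 7009 and 1541 ± 518, and Guca2a 312 ± 211 and 2576 ± 975.

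Most transcripts of the epithelial, gastric, immediate early and MAP kinase lists had lower mean values in mA1 libraries, with mA1 library 2 the lowest in each list. In the last 3 lists the groups overlapped: 1 mA1 library lay above 1 control library by the median over members. Of 25 epithelial junction and keratin genes 23 had lower values, with a median log2 fold change of −0.41. Of 25 genes of gastric and gut endoderm, a programme seen in lung tumour cells that lose their lung identity, 20 were lower, with a median of −1.03. Of 26 immediate early and stress genes 23 were lower (median −0.53), and of 21 genes that report MAP kinase signalling 16 were lower (median −0.27). By camera with the preset correlation these lists fell, with adjusted p of 4.49e-06 for junctions, 2.04e-05 for gastric endoderm, 2.04e-05 for immediate early genes and 0.00224 for MAP kinase output. None of the 4 calls held with an estimated correlation (adjusted p = 0.691 for each), and fry's directional test passed none of these lists. With the preset correlation all 4 lists passed camera whichever library was left out (largest adjusted p = 0.0282, MAP kinase output without control library 2). They also passed after GC correction, with camera adjusted p from 0.000140 for gastric endoderm to 0.00863 for MAP kinase output. Without mA1 library 2 the median was −0.22 for junctions and −0.57 for gastric endoderm, which had −1.48 without mA1 library 3. The immediate early median was −0.27 without control library 1 and −0.33 without mA1 library 2, with −0.82 without control library 3, and the MAP kinase median was −0.14 without control library 2 and −0.43 without control library 3.

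Single members of these lists passed only when adjusted over the list alone, and 0 passed over all genes in limma, where Ly6d was the 1 passing gene. In the gastric list 8 members passed adjusted over the list alone: Tff3, Lgals4, Agr2, Tff1 and the transcription factor genes Hnf4a, Foxa3 and Cdx2 were lower, and the apolipoprotein gene Apoa1 was higher. Hnf4a (chromosome 2, 163506808 to 163572910) had 10174 ± 3535 normalised counts in control and 4114 ± 1126 in mA1 libraries, and Lgals4 46450 ± 13907 and 15212 ± 9427. Nr4a1 and Egr3 passed among immediate early genes, with 18456 ± 4243 and 9119 ± 1120 for Nr4a1. Spry4 and Dusp4, feedback inhibitors of the MAP kinase pathway, passed in the MAP kinase list, and Spry4 (chromosome 18, 38586247 to 38601415) had 4562 ± 439 and 2350 ± 164. In the junction list 0 members passed adjusted over the list alone. The authors' deposited table calls Krt8 (−0.74), Krt18 (−0.75), Fosb (−1.60), Dusp5 (−1.29), Spry4 (−0.96), Dusp4 (−1.09), Nr4a1 (−1.02) and Egr3 (−5.55) lower, and in the gastric list Agr2, Cdx2, Foxa3, Hnf4a, Lgals4 and Tff3. After GC correction DESeq2 no longer called Krt8 (log2 fold change −0.58), Krt18 (−0.62), Fosb (−1.51), Dusp5 (−1.16) and Cdx2 (−2.79, from −3.05). Without control library 1 DESeq2 no longer called Fosb (−1.07), Egr3 (−4.62), Dusp4 (−0.96), Lgals4 (−1.54, from −1.61), Agr2 (−1.12, from −1.11) and Cdx2 (−3.25). Folds such as those of Lgals4, Agr2 and Cdx2 changed little, so their lost calls do not show that the difference went away. Over all lists 25 members were called in the authors' deposited table, of which DESeq2 called 15 after GC correction and 16 without control library 1.

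**Figure D2:**
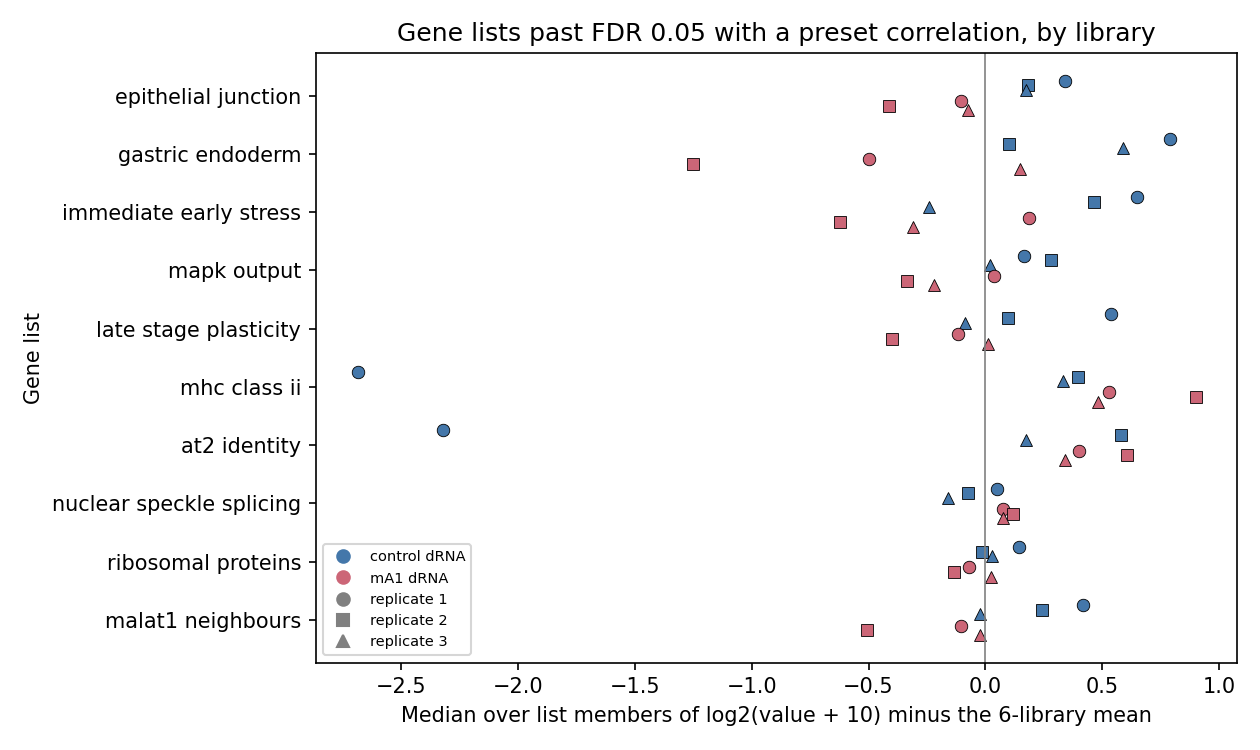
Median over list members of log2(value + 10) minus the 6-library mean, by library, for the 10 lists past FDR 0.05 with a preset correlation. Control library 1 lies at −2.32 for alveolar type 2 genes and −2.69 for class II genes, apart from the other 5 libraries.

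Genes of alveolar type 2 cells, the surfactant-making cells from which these tumours commonly arise, and genes of class II antigen presentation had higher values in mA1 libraries, and 1 control library carried that difference. Of 21 type 2 genes 19 were higher, with a median log2 fold change of 0.94, and all 8 class II genes were higher, with a median of 1.31. Both lists rose by camera with the preset correlation (adjusted p = 0.00896 for each), and neither call held with an estimated correlation (adjusted p = 0.691 for each). Sftpc, which encodes surfactant protein C, took 0.679%, 7.81% and 7.85% of exonic reads in control libraries and 7.24%, 12.2% and 7.21% in mA1 libraries. Without control library 1 the type 2 list had a median of −0.0203 (limma's camera, adjusted p = 0.999) and the class II list a median of 0.26 (limma's camera, adjusted p = 0.0239). No member of either list passed over all genes or adjusted over the list alone in limma. Late-stage plasticity genes, listed as marks of advanced tumours, fell by camera (16 of 22 lower, median −0.32, adjusted p = 0.00896; adjusted p = 0.691 with an estimated correlation). That list had a camera adjusted p of 0.181 without control library 1 (median −0.14), 0.0975 without mA1 library 2 (−0.21) and 0.000540 without control library 3 (−0.50), and the authors' deposited table calls its members Krt8 and Plaur lower.

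Genes of nuclear speckles and splicing, the structures in which Malat1 resides, had slightly higher values in mA1 libraries, and ribosomal protein genes slightly lower ones. Of 28 speckle genes 21 were higher, with a median log2 fold change of 0.10, and of 29 ribosomal protein genes 24 were lower, with a median of −0.11. By camera with the preset correlation the first list rose (adjusted p = 0.00985) and the second fell (adjusted p = 0.0104), and each call was lost with an adjusted p = 0.691 with an estimated correlation. Pnisr, Luc7l3 and Tra2a passed adjusted over the list alone, with 0 over all genes in limma, and Pnisr (chromosome 4, 21847583 to 21876475) had 6687 ± 567 and 10084 ± 418 normalised counts. After GC correction the speckle list had a median of −0.0395 (camera adjusted p = 0.733), and Pnisr, Luc7l3, Tra2a and Srsf10, the 4 members called higher in the authors' deposited table, were no longer called by DESeq2. The speckle list had a camera adjusted p of 0.0638 without control library 2, 0.105 without control library 3 (median 0.0485) and 0.000174 without control library 1 (0.18), and the ribosomal list 0.147 without control library 1 (−0.0549) and 0.105 without mA1 library 2. Nuclear-retained long noncoding RNAs did not pass (limma's camera, adjusted p = 0.779, direction down, although the median was 0.29 and the mean 0.14), but passed fry's mixed test for change in either direction (adjusted p = 9.83e-05). Within that list Gm42418 and Gm26917, loci that carry ribosomal RNA sequence, were lower adjusted over the list alone, with 179188 ± 62756 and 81978 ± 8346 normalised counts for Gm42418.

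**Figure D3:**
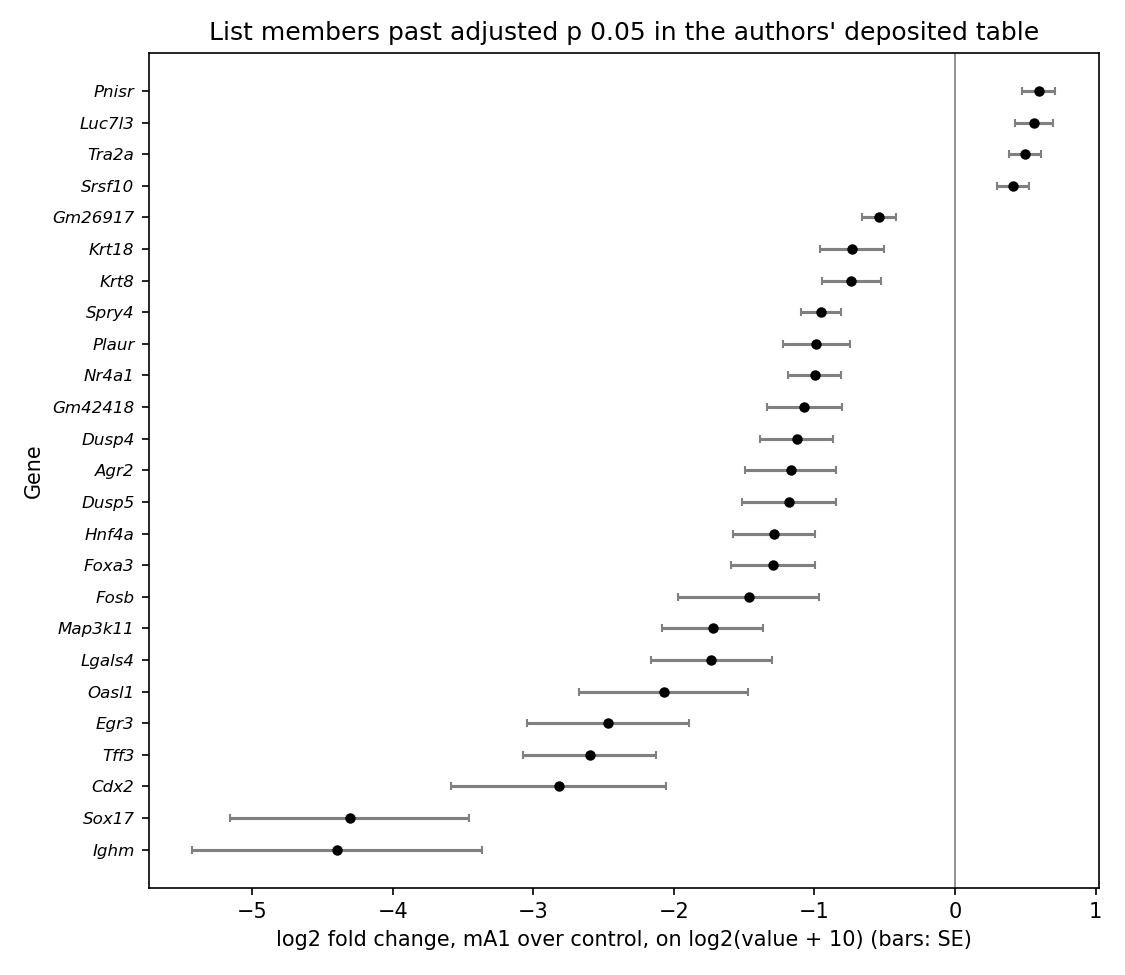
Log2 fold change, mA1 over control on the log2(value + 10) scale, with bars for the SE, of the 25 list members past adjusted p 0.05 in the authors' deposited table. On the lower side lie 21 genes and on the higher side 4, all of them speckle genes.

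Chemokine and cytokine genes did not pass as a set (limma's camera, adjusted p = 0.267), with 13 of 35 members higher and 22 lower. Ccl2, a monocyte-attracting chemokine (chromosome 11, 82035571 to 82037453), had 0, 0 and 26.1 normalised counts in control and 27.9, 170.8 and 53.6 in mA1 libraries, which did not pass (log2 fold change 2.30, limma adjusted p = 0.324). It overlaps Gm17268 on the opposite strand, so its count is uncertain. The osteopontin gene Spp1 had 500123 ± 304483 and 214446 ± 105434, and the alarmin gene Il33 15317 ± 11528 and 34950 ± 3788, neither past the threshold. Camera adjusted p was 0.366 for NF-kB targets, 0.123 for interferon response, 0.105 for class I antigen presentation, 0.193 for proliferation, 0.0711 for hypoxia and glycolysis, 0.366 for alveolar type 1 and 0.270 for airway genes. Class I genes passed camera after GC correction (adjusted p = 0.0198) and with the replicate block (adjusted p = 0.0274). Their camera adjusted p was 0.669 without control library 1 and 0.691 with an estimated correlation. Mesenchymal genes had a camera adjusted p of 0.0870, with 0.0361 without control library 1 and 0.0367 after GC correction. It was 0.691 with an estimated correlation, and 11 of 18 mesenchymal genes were higher in the full set. Oasl1, an interferon-induced gene, is called lower in the authors' deposited table (log2 fold change −1.90).

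Markers of cells that the sort should remove did not pass as sets by camera, while endothelium passed fry's mixed test (adjusted p = 0.0209), and some of the listed genes were abundant. Msln had 47428 ± 13420 normalised counts in control and 32792 ± 15392 in mA1 libraries, and Plac8 31283 ± 9966 and 10262 ± 8678. Camera adjusted p was 0.189 for macrophages, 0.482 for neutrophils and monocytes, 0.656 for lymphocytes, 0.366 for endothelium, 0.697 for fibroblasts and mural cells, 0.476 for erythroid cells and platelets and 0.0560 for mesothelium. With the replicate block mesothelium passed camera (adjusted p = 0.0238), while an estimated correlation gave it a camera adjusted p of 0.691. Of the 8 mesothelial genes 3 were measured, among them Krt19, which is also in the epithelial junction list. Ptprc, which encodes CD45, had 223 ± 71.7 normalised counts in control and 158 ± 66.6 in mA1 libraries, beside 66965 ± 12426 and 50880 ± 11581 for Epcam. Ighm, the immunoglobulin mu gene, had 0 in every mA1 library and 770.6, 29.3 and 292.9 normalised counts in control, most of them in control library 1, and passed adjusted over the list alone. In the endothelial list Sox17 was lower and Pecam1 higher adjusted over the list alone, and Pecam1 had 37.5, 23.7 and 4.51 normalised counts in control and 120.5, 107.1 and 110.2 in mA1 libraries.

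Intronic reads, which come largely from unspliced transcripts, gave 0 of 12791 genes past FDR 0.05 in limma, with 1343 genes at unadjusted p under 0.05 (702 higher and 641 lower). edgeR with TMM factors and limma-voom also called 0, edgeR with 1038 genes at unadjusted p under 0.05 and limma-voom with 1369, while DESeq2 on recovered reads called 143. The authors' deposited table lists 143 intronic genes past adjusted p 0.05, 71 higher and 72 lower, and they were the 143 that DESeq2 called. Without control library 3 DESeq2 called 257 higher and 85 lower, without control library 1 184 and 66, and without mA1 library 3 60 and 182. In 139 of those of the authors' deposited table the groups did not overlap, a pattern found in 16.4% of all intronic genes where chance gives 10%. The 10 genes with the smallest limma p (adjusted p = 0.296 for each) held 9 lower and 1 higher. The stress kinase gene Plk3 had 1543 ± 483 normalised intronic counts in control and 293 ± 110 in mA1 libraries, Gucd1 906 ± 129 and 171 ± 90.8, and Card19 898 ± 35.7 and 309 ± 54.1. Dscam, a neuronal adhesion gene, was 0 in every mA1 library, at least 51.6-fold lower, and the oncogene Mycn was 0 in every control library, at least 24.7-fold higher. Grik4 had 626 ± 332 and 55.4 ± 35.8. Gm12146, Gm10069 and Gata5os are antisense genes that overlap Atp10b, Pzp and Gata5, and Plk3, Gucd1 and Sfta2 also overlap genes on the opposite strand, so these counts are uncertain. The largest calls of the authors' deposited table were ranked among genes with a mean CPM of at least 5 and no overlap between groups. On the higher side these were Zswim5, Hgd, Amph, Gramd1a and 5730522E02Rik, and on the lower Dscam, Tprn, Fa2h, Tmprss6 and Grik4. Mycn, at a mean CPM of 4.46, had a larger log2 fold change in the authors' deposited table (8.67, against 8.04 for Zswim5).

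The last comparison asked whether exonic and intronic reads of a gene moved apart, as they would if transcript stability or processing differed between groups. Of 11656 genes 0 passed FDR 0.05 in limma (smallest adjusted p = 0.525), with 848 at unadjusted p under 0.05, and edgeR's interaction test with TMM factors also called 0, with 710 at unadjusted p under 0.05. Gramd1a had an exonic log2 fold change of −0.0617 and an intronic one of 3.25, and Nupl2, Mnd1, Efna4 and Atad5 also had a more positive intronic than exonic value. St6galnac4 went the other way, with an exonic minus intronic log2 fold change of 2.67 (SE 0.41), as did Pde1b, Serpinh1, Tprn and M1ap. Across genes, which are not independent replicates, exonic and intronic log2 fold changes had a Pearson r of 0.546 and a Spearman rho of 0.500. In introns, 366 of the exonic calls in the authors' deposited table were measured and 333 of these had the same direction there. All 23 genes called in both parts of the authors' deposited table had the same direction. Intronic reads made up 10.2% ± 1.07 of recovered reads in control libraries and 11.5% ± 0.477 in mA1 libraries, a difference of 1.32 percentage points (0.821 without control library 2 and 1.89 without control library 1). That difference was not past the threshold (two-sided exact permutation p = 0.2, where the smallest possible p is 0.1).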

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

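Chosen after the results were seen were the tests with other pseudocounts, TMM factors, array weights and GC correction (alone or with the block) for genes, pseudocounts, TMM factors and GC correction for lists, and all alternatives for DESeq2 calls; the rest were fixed before the data were examined. The alternatives fixed for the number of lists were given for single lists too, a choice made afterwards. Ly6d had a log2 fold change from −2.08 to −1.90 in all settings run. Exonic genes past FDR numbered 1 in limma and 0 in edgeR with TMM, RLE or upper-quartile factors, 0 with the replicate block, 0 with GC correction and the replicate block together, 478 in DESeq2, and 0 to 1 leaving out each library. At unadjusted p under 0.05, leaving out each library gave 1338 (without mA1 library 2) to 2186 exonic and 763 (without mA1 library 2) to 1551 intronic genes. DESeq2 exonic calls ranged from 243 (without mA1 library 2) to 773 (without control library 2), with 268 without mA1 library 1 and 770 without mA1 library 3, and numbered 315 with an absolute log2 fold change of at least 1. Intronic genes past FDR numbered 0 in limma, 143 in DESeq2, and 0 to 1 leaving out each library. The 1 was Fuom without mA1 library 3. DESeq2 intronic calls ranged from 51 (without mA1 library 2) to 342 (without control library 3), with 69, 250 and 242 without mA1 library 1, control library 1 and mA1 library 3. Lists past FDR numbered 10, against 0 with an estimated correlation, 0 by fry and 7 to 13 leaving out each library. The type 2 list had a median of −0.0203 without control library 1, in a range to 1.40, and the speckle list −0.0395 with GC correction. Dpf2 ranged from −0.0285 to 0.14 leaving out each library and was −0.0260 with GC correction, with or without the replicate block. Ltbp3 ranged from −0.23 to 0.0127 and was 0.12 with GC correction, with or without the replicate block. Fewer libraries lower the power of a test; beyond that the cause was not tested. Over 43 named genes, 802 settings left the call and direction as they were, and 33 genes passed only with DESeq2. No pairing of the animals by number was seen: same-numbered libraries deviated from their group means with correlations of 0.0187, 0.0659 and −0.102 in exons, and not every library correlated best with its own number. With 3 libraries per group this cannot exclude a batch shared by number. The replicate block gave 0 intronic genes, 0 exon against intron genes, 12 lists and 693 exonic DESeq2 calls. Alternatives for Malat1 were not run.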

Other observations

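Chosen after the results were seen were the tests of transcript length, depth, the GC trend by library, a wrong label and dilution by other cells, the splits for exonic counts, and the genes named in the next paragraph.

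Ly6d was also lower in its introns, with 360 normalised intronic counts in control and 42.1 in mA1 libraries (log2 fold change −2.76; limma adjusted p = 0.296). Its relatives did not share one direction in exons: Psca had a log2 fold change of −1.94, Ly6a −1.03, Ly6e −0.29, Ly6c1 −0.11 and Ly6i 2.12, with none past the limma threshold. The noncoding genes C130075A20Rik and Gm42899 both lie within Lhfp, and Lhfp itself had an intronic log2 fold change of 1.48 and an exonic one of 0.35. Atp10b was lower in exons (−2.36) as its antisense partner Gm12146 was in introns (−2.88), and Pzp was lower in exons (−2.45) as its partner Gm10069 was in introns (−1.88). The transcription factor gene Gata5 had −2.06 in exons and its partner Gata5os −2.69 in introns, and without strand each pair shares reads. Mycn, at 0 in control introns, had 876 exonic counts in control and 2556 in mA1 libraries (limma adjusted p = 0.338).

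Camera with the preset correlation, planned only for exons, was also run on intronic lists. The intronic medians were −0.35 for epithelial junctions (camera adjusted p = 0.0182) and −0.50 for gastric endoderm (camera adjusted p = 0.0331). They were −0.40 for immediate early genes (camera adjusted p = 0.0187) and −0.32 for MAP kinase output, which did not pass (camera adjusted p = 0.275). Type 2 genes had 1.00 (camera adjusted p = 0.0182) and class II genes 1.03, which did not pass (camera adjusted p = 0.0656). Speckle genes had −0.0544 (camera adjusted p = 0.746) and ribosomal protein genes −0.00891 (camera adjusted p = 0.929). Malat1 neighbours had −0.61 and late-stage plasticity genes −0.38 (camera adjusted p = 0.0292 for each). An estimated correlation, which ended every list call in exons, was not run for intronic lists, nor was leaving out libraries.

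The genes called lower in the authors' deposited table had a median transcript GC content of 55.7% and those called higher 44.8%, beside 49.3% over all genes, and the difference shrank to 51.1% against 47.8% among the DESeq2 calls made after GC correction. The correction for GC content kept 64.2% of the DESeq2 exonic calls in the same direction (307 of 478), above the bound set beforehand for a GC trend as the cause. That cannot rule out a GC trend as the whole cause, since the correction used 1 transcript per gene and a GC difference remained among the corrected calls. The Spearman correlation of fold change with transcript length was 0.0194 (−0.288 with GC), which argues against length. A ratio of total reads of 1.02 argues against depth. Some calls ended under the correction, such as Pnisr, whose DESeq2 log2 fold change went from 0.59 to 0.41 (SE 0.14, adjusted p = 0.113), a smaller fold at a similar error. Each control library correlated with GC positively (0.0707, 0.21 and 0.31) and each mA1 library negatively (−0.17, −0.20 and −0.19), for which the exact two-sided permutation p of 0.1 is the smallest possible. A GC bias between libraries and a difference between the groups cannot be told apart for this trend, since it runs along the groups.

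Control library 1 had 20 of 21 type 2 transcripts below the mean of the other 5 libraries, with a median log2 difference of −2.78, and Sftpc was 12.7-fold lower than in the other libraries. Epcam in that library was 1.49 times the mean of the other 5, which argues against dilution by non-epithelial cells. The log2 differences of the members ran from −3.64 to 0.15. Their interquartile range of 0.963 lay just under the bound of 1 set beforehand for a smaller share of one type 2 cell population. With so wide a range this does not show that the members fell by the same amount. Some markers of other cells were low in that library too. Ager had 15812 normalised counts against 128214 to 238020 in the other 5, Cbr2 2176 against 22163 to 33359, and Sparc 2430 against 21686 to 47820. Other cell lists went either way there by the median deviation from the 6-library mean. Alveolar type 1 (−1.42), mesenchymal (−0.52) and airway genes (−0.14) lay below it, as did lymphocyte, fibroblast and erythroid markers. Macrophage (0.33), neutrophil and monocyte (0.70), mesothelial (0.34), endothelial (0.20) and gastric genes (0.79) lay above it. The mesothelial value rests on 3 measured genes, among them Krt19 of the epithelial junction list, so it need not reflect mesothelial cells. Type 2 cells alone would not account for the library, and the explanation stays open. A wrong label on it stays open: of the 402 genes DESeq2 called without that library, 74.1% (298) lay nearer to the other controls, between the bounds set for either reading.

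The 6 libraries divide into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1 exonic gene past FDR in limma (highest other 0), 2096 at unadjusted p under 0.05 (highest other 1118), and 478 by DESeq2 (highest other 70), each reached by 1 of the 10 splits. DESeq2 gave 143 intronic genes (highest other 50), also reached by 1 split. In limma all 10 splits gave 0 intronic genes and 0 exon against intron genes past FDR. For the lists by camera 6 of the 10 splits gave as many as the real 10, with 14 the highest other.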
